A study of Acetivibrio thermocellus DSM 1313 with 14 samples.

How the data were processed

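RNA of 10 samples, 2 from each of 5 strains, had been converted to ds-cDNA and hybridised with Cy3 label to 14 arrays, per the labels' protocols. Growth was at 60°C in shaken cultures (150 rpm). Replicate 2 of CTN4 and replicate 1 of CTN5, CTN7 and DS3 each had 1 repeat array. The arrays fell on 3 slides: slide 1 held both replicates of CTN4, CTN5 and CTN7, slide 2 the 4 repeats, and slide 3 both replicates of DS3 and DS11. Per the file headers, the spot intensity on each array was read with NimbleScan 2.4.27. Array medians differed, so the deposited intensities were judged not to be normalised between arrays. The medians do not show whether background had been subtracted. A deposited table for the whole series holds log2 values, which equalled log2 of those intensities to within 5e-08 and were therefore used only as an alternative. Each array has 137010 spots, on a design for the type strain of the species. The design has 21335 gene probes for 3065 genes, up to 7 per gene and 3 spots each, 22176 tiling probes between genes, and 6477 random spots. The samples are of another strain, so a difference in sequence would lower a probe's signal in all 5 strains.

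Spot intensities were corrected with limma's normexp (offset 50), quantile normalised over all spots and log2 transformed. The 3 spots of a probe were averaged, and the probes of a gene summarised by median polish. Probes of a gene that disagree are down-weighted by this, and the mean of probes was an alternative. Repeat arrays were averaged with the replicate of the same number. Tools were R 4.3.3, limma 3.58.1 and the package data.table (1.17.8). A linear model over all 10 samples, with strain as the factor, gave log2 fold changes, SE and moderated tests with 5 residual and 2.8 prior degrees of freedom. The model takes the same spread for every strain. The SD of the log2 difference between replicates was 0.864 in CTN5 and from 0.151 (CTN7) to 0.327 (DS3) in the other strains. Tests with CTN5 may therefore be too lenient and the other tests too strict. Every adjusted p is from limma, with the Benjamini-Hochberg method over the 3065 genes within a comparison, and genes were called at 0.05. The tests are two-sided. Between 63.3% and 77.3% of genes had both replicates of a strain beyond both of the other strain, against 33.3% by chance. That chance value holds only if samples are exchangeable, whereas slides and averaged repeats can also set strains apart. The share did not follow the calls: it was 68.5% in CTN7 against CTN4, with 38 genes called, and 63.3% in CTN5 against DS3, with 1206. It is therefore no measure of strain differences.

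The files carry no detection flags. Background was set per array at the 95th percentile of the random spots after normalisation, and a gene below it on every array of a strain has only a bound there. The bound sets the bright strain's mean against the mean of, per array, the higher of that limit and the gene's own signal, and is given as "at least N-fold". No size is given for a gene below it on 2 of the 3 arrays of a strain, and a log2 change is printed where at most 1 array of the dim strain lay below it.

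No genome or annotation of the strain was used, and the files do not pair locus tags with gene names. Genes are given by the locus tags of the array design. Names of scaffoldins come from general knowledge and were fixed with their tags before the data were examined, as were the 74 tags of the dockerin list, which were checked against no table. Of 22 lists planned, the 20 that needed product names could not be filled. Lists were tested with limma's camera (preset correlation 0.01, lists of 3 or more genes), repeated with an estimated correlation. Because camera takes no random block, cameraPR on the moderated statistics was used there. The rule for named genes, also fixed before the data were examined, took every scaffoldin. It also took the largest rises and falls with non-overlapping replicates and the same sign on slide 2 (slide 3 for DS11), and the leading members of called lists. Its part on fermentation and sugar uptake needed product names and was left out. Without a table of names, at most 2 tags that rose and 2 that fell are given per comparison outside the lists.

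The slide block was a fixed term over the 14 arrays, with arrays of one RNA sample correlated at 0.564 (duplicateCorrelation). Alternatives also covered background correction, median scaling, a filter on dim genes, the replicate number as a block, leaving out the repeats, the deposited table and leaving out each replicate. Settings added after the data were seen were the median of spots, leaving out a hazy DS3 repeat array, leaving out CTN5 replicate 2 from every comparison, averaging each repeat with the other replicate, and array weights. The linear model, but not the processing before it, was tested on simulated log2 gene values for CTN4 against DS3. Of 3065 genes 200 were changed. The model recovered 65% of the 2-fold and 98% of the 4-fold changes with 4 false calls. With simulated slide effects, the model without a slide term made 59 false calls (27.3% of its calls) and the slide block 7 (4.6%), recovering 52% of the 2-fold and 93% of the 4-fold changes. For that reason slide-block counts are given beside the counts of called genes in each comparison. The simulated slide effect had a chosen size, not one estimated from these arrays, and all strains were given the same spread. The simulated rates therefore do not describe the real comparisons.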

Results

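Acetivibrio (Clostridium) thermocellus is a thermophilic anaerobic bacterium that degrades cellulose with cellulosomes, large enzyme complexes built on non-catalytic scaffold proteins called scaffoldins. Enzymes carry a dockerin domain, which binds the cohesin domains of a scaffoldin. Transcript levels were measured on 14 single-colour arrays in 5 strains, named CTN4, CTN5, CTN7, DS3 and DS11. Per the labels, strains with different scaffoldin genes deleted were compared. The labels do not say which strain lost which gene and name no parent strain, so DS3 served as the reference for 4 comparisons, and the CTN strains were also compared with each other in 3. Cells were grown on Avicel, a crystalline cellulose, and harvested when 50% of it had been converted. Each strain had 2 replicates, and 4 of the 10 RNA samples were also hybridised to a repeat array. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. Median gene signal was 4.39 times the median signal of random probes on the first array of CTN4 replicate 2, the lowest ratio, and up to 41.8 times on the others. The number of arrays limits the precision. Across genes, which are not independent replicates, replicates of CTN5 correlated at 0.926 and those of the other strains at 0.989 or above. These values have the repeat arrays averaged in. Between the first arrays alone, the correlation was 0.978 in CTN4, 0.979 in DS3 and 0.993 in CTN7, so the averaging raised the agreement there.

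The first question was which scaffoldin genes were transcribed in each strain. CipA (Cthe_3077), the primary scaffoldin that holds the enzymes, had a log2 signal of 15.20 ± 0.03 (SD, n = 2) in DS3 and 15.45 ± 0.09 in CTN5. It lay below background on all arrays of DS11, at 8.57 ± 0.42, and of CTN4, at 8.56 ± 0.03. In CTN7 it averaged 9.04 ± 0.54 and was below background on 2 of 3 arrays. OlpB (Cthe_3078), Orf2p (Cthe_3079) and SdbA (Cthe_1307), which anchor cellulosomes to the cell surface, and the surface protein OlpA (Cthe_3080) were bright in DS3, between 14.40 ± 0.07 and 14.95 ± 0.11. They were as bright or close to it in DS11, between 14.23 ± 0.02 and 15.40 ± 0.03. All of these surface genes lay below background on every array of CTN4, CTN5 and CTN7, with means from 7.59 ± 0.15 to 8.51 ± 0.51. OlpC (Cthe_0452), another surface protein, was below background on all 3 arrays of CTN7, at 9.10 ± 0.05, and bright in DS3 (15.09 ± 0.23), CTN5 (15.07 ± 0.16), CTN4 (14.27 ± 0.09) and DS11 (14.08 ± 0.14). The scaffoldin genes Cthe_0735 and Cthe_0736 were above background on every array. All 8 scaffoldin loci were above background on every array of DS3, so the signals show no loss of any of them there. Per the labels strains with deleted scaffoldin genes were compared, so a signal below background may mark a deleted gene. A fall of the scaffoldin list in the tests below then follows from how the strains were made and is no separate finding.

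**Figure D1:**
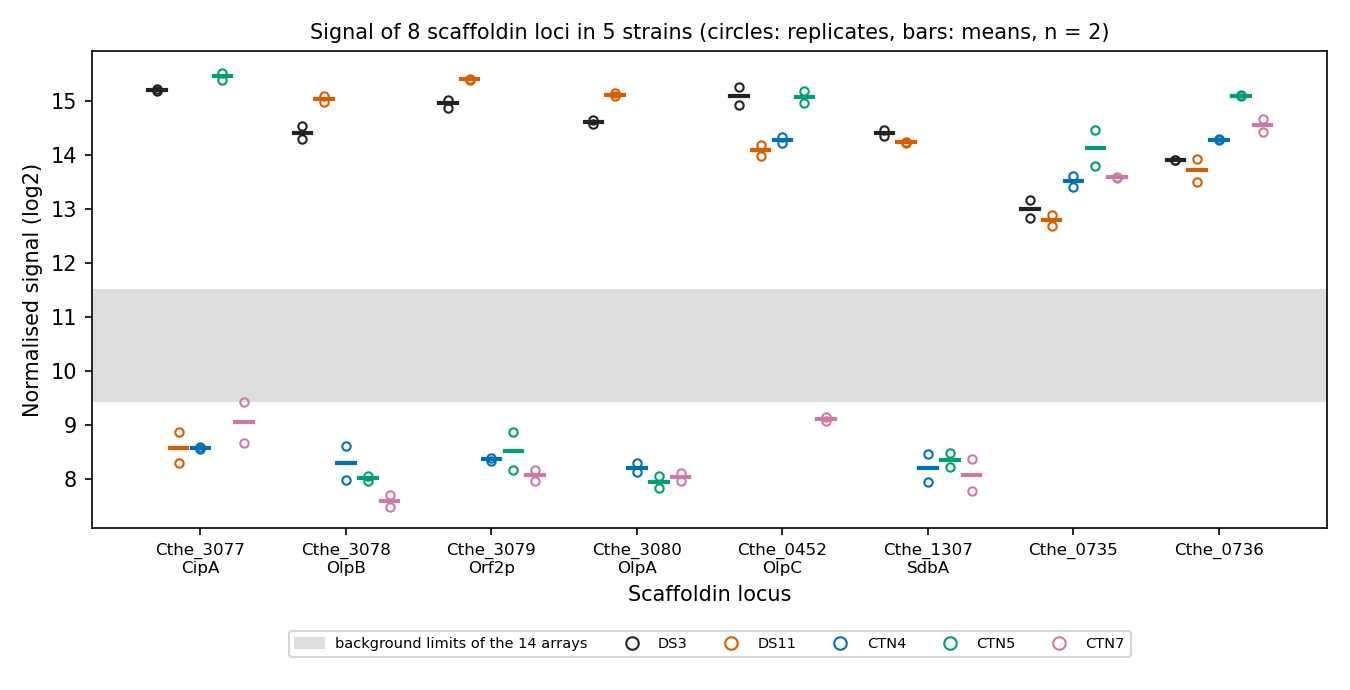
Normalised signal (log2, y axis) of the 8 scaffoldin loci (x axis) in the 5 strains, with circles for the 2 replicates, bars for their means and a grey band for the background limits of the 14 arrays. OlpC was below background in CTN7, at 9.10, and lay at 14.08 or above in the other strains.

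In DS11, CipA was at least 47.7-fold lower than in DS3 (adjusted p = 7.43e-06), and 40 of the 74 dockerin loci rose while 2 fell and 32 were not called. The rises included Cthe_2138, by 3.31 on the log2 scale (SE 0.51, adjusted p = 0.00197), Cthe_2139, by 3.14 (SE 0.29), and Cthe_2590, by 3.05 (SE 0.17). Cthe_2179 fell by 1.99 (SE 0.23, adjusted p = 0.000448). OlpC fell by 1.00 (SE 0.17, adjusted p = 0.00297) and, with median scaling, this call was lost (adjusted p = 0.143). Outside the lists, Cthe_0502 was at least 8.94-fold higher, Cthe_0446 rose by 3.82 (SE 0.20), Cthe_1524 fell by 4.82 (SE 0.22) and Cthe_0038 fell by 4.56 (SE 0.55). In all, 965 genes were called (482 higher, 483 lower), 292 of them higher and 317 lower by 2-fold or more. The dockerin list stood above the other genes (camera adjusted p = 1.58e-11, and adjusted p = 0.0327 with an estimated correlation), with a median log2 change of 0.71 against -0.05. Adjusted over the list alone, 49 members rose and 2 fell. The scaffoldin list as a whole was not called (camera adjusted p = 0.475, and adjusted p = 0.582 with an estimated correlation). DS11 shared a slide with DS3. With slide as a block 826 genes were called, 796 of them among the 965 in the same direction, 31 dockerin loci rose and 2 fell, and the list median was 0.70, as it was within the slide. The OlpA rise of 0.51 (SE 0.15, adjusted p = 0.0304) was lost with the block (adjusted p = 0.265) and without any 1 of the replicates: adjusted p was 0.122 without DS11 replicate 1, 0.146 without DS11 replicate 2, 0.118 without DS3 replicate 1 and 0.0833 without DS3 replicate 2. Without DS11 replicate 1, 567 genes were called, without DS11 replicate 2 598, and with median scaling 608, while 1632 were called when CTN5 replicate 2, which enters only the shared estimate of the spread, was left out and 1477 with array weights. The dockerin loci that rose numbered 21 without DS11 replicate 1, 25 without DS11 replicate 2, 26 with median scaling and 26 without the repeat arrays.

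In CTN4, 5 scaffoldin genes were below background and lower than in DS3, CipA by at least 34.6-fold, Orf2p by at least 29.1-fold, OlpA by at least 22.9-fold, OlpB by at least 20.0-fold and SdbA by at least 19.8-fold (the highest of the 5 adjusted p-values was 7.9e-06, for CipA). Of the 74 dockerin loci 47 rose, 1 fell and 26 were not called. The largest rises on the list were those of Cthe_2138, by 4.03 (SE 0.51, adjusted p = 0.00107), Cthe_3141, by 3.60 (SE 0.38), Cthe_2139, by 3.40 (SE 0.29), and Cthe_2590, by 3.13 (SE 0.17), and the fall was that of Cthe_2179, by 1.67 (SE 0.23). OlpC fell by 0.82 (SE 0.17, adjusted p = 0.00954), a call that was lost with slide as a block (adjusted p = 0.159), with median scaling (0.298), without CTN4 replicate 1 (0.0666) and without DS3 replicate 1 (0.0627). Outside the lists, Cthe_0197 rose by 3.03 (SE 0.26), Cthe_1081 was at least 2.52-fold higher, Cthe_2236 fell by 4.07 (SE 0.21) and Cthe_1498 was at least 10.8-fold lower. In all, 873 genes were called (570 higher, 303 lower), 287 higher and 190 lower by 2-fold or more. Both lists were called, the dockerin list upward (camera adjusted p = 9.84e-11, and adjusted p = 0.019 with an estimated correlation; median 0.82 against 0.15 for other genes) and the scaffoldin list downward (adjusted p = 6.78e-08, and adjusted p = 0.0134 with an estimated correlation). Adjusted over the list alone, 52 dockerin loci rose and 2 fell. With slide as a block 516 genes were called, 478 of them among the 873 in the same direction, the dockerin median was 0.96, and 39 members rose and 1 fell. On slide 2, the only slide with both strains and with 1 array of each, the dockerin median was 0.95. Counts fell to 447 without CTN4 replicate 1, 496 without CTN4 replicate 2, 476 without DS3 replicate 1 and 456 with median scaling, and rose to 1528 when CTN5 replicate 2 was left out of the shared spread. Only 28 dockerin loci rose without CTN4 replicate 1, and 28 with median scaling.

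CTN5 kept a bright CipA signal, 0.25 above that of DS3 (SE 0.27, adjusted p = 0.499) and -0.46 from it with slide as a block (adjusted p = 0.765). Orf2p was at least 23.7-fold lower, OlpA at least 18.7-fold, OlpB at least 16.4-fold and SdbA at least 16.2-fold (highest adjusted p = 7.43e-06). Cthe_0736, a scaffoldin gene, rose by 1.20 (SE 0.17, adjusted p = 0.00147), a call lost with array weights (adjusted p = 0.0962). Cthe_0735 rose by 1.13 (SE 0.24, adjusted p = 0.00744), a call lost with slide as a block (adjusted p = 0.0501), without DS3 replicate 2 (0.0531) and with array weights (0.0586). Of the dockerin loci 35 rose, 4 fell and 35 were not called. Cthe_2950 rose by 2.72 (SE 0.26), Cthe_2147 by 2.53 (SE 0.19), Cthe_0190 by 2.48 (SE 0.19) and Cthe_3012 by 2.37 (SE 0.14, adjusted p = 6.79e-05), while Cthe_3136 fell by 2.38 (SE 0.17) and Cthe_2179 by 1.94 (SE 0.23). Outside the lists, Cthe_2507 and Cthe_1438 were called higher and were above background on all arrays of CTN5 but on only 1 of 3 of DS3, so no size is given, Cthe_2556 was at least 8.29-fold lower and Cthe_0809 fell by 3.37 (SE 0.18). In all, 1206 genes were called (498 higher, 708 lower), 275 higher and 425 lower by 2-fold or more. The dockerin list was called upward (camera adjusted p = 3.53e-10, and adjusted p = 0.0424 with an estimated correlation; median 0.75 against -0.06). Adjusted over the list alone, 40 dockerin loci rose and 4 fell. The scaffoldin list was called downward (adjusted p = 0.0298), and adjusted p = 0.134 with an estimated correlation; that call was also lost without CTN5 replicate 1 and without DS3 replicate 1, which each left 1 list called. With slide as a block 891 genes were called, 811 of them shared in direction, and the dockerin median was 0.64, with 29 members higher and 2 lower. Within slide 2 the dockerin median was 0.85. The count of genes was 1853 without CTN5 replicate 1, 777 without DS3 replicate 2, 622 with median scaling and 514 with array weights. Dockerin loci rose in 41 cases and fell in 9 without CTN5 replicate 1, and 51 rose without CTN5 replicate 2, 25 with median scaling and 20 with array weights.

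CTN7 had the same low surface scaffoldins and, in addition, a low OlpC. OlpC was at least 42.7-fold lower than in DS3 (adjusted p = 1.02e-06), Orf2p at least 38.8-fold, OlpA at least 30.6-fold, OlpB at least 26.7-fold and SdbA at least 26.5-fold, and CipA was called lower, with no size given because it was above background on only 1 of 3 arrays. Cthe_0736 rose by 0.66 (SE 0.17, adjusted p = 0.0269), a call lost with slide as a block (adjusted p = 0.0702), with median scaling (0.214), and without CTN7 replicate 1 (0.0762), CTN7 replicate 2 (0.187), DS3 replicate 1 (0.103) or DS3 replicate 2 (0.0953). Of the dockerin loci 47 rose, 2 fell and 25 were not called. Cthe_2138 rose by 4.36 (SE 0.51, adjusted p = 0.000769), Cthe_3141 by 3.67 (SE 0.38), Cthe_0044 by 3.49 (SE 0.14) and Cthe_2139 by 3.46 (SE 0.29), and Cthe_2179 fell by 1.39 (SE 0.23). Outside the lists, Cthe_2293 was at least 3.40-fold higher (adjusted p = 0.00676, and 0.0527 without CTN7 replicate 2), Cthe_2292 was at least 2.24-fold higher and Cthe_2232 fell by 4.08 (SE 0.30). In all, 777 genes were called (491 higher, 286 lower), 247 higher and 185 lower by 2-fold or more. The dockerin list was called upward (camera adjusted p = 6.6e-15; median 0.89 against 0.08) and the scaffoldin list downward (adjusted p = 2e-08), each with adjusted p = 0.00938 with an estimated correlation. Adjusted over the list alone, 52 dockerin loci rose and 2 fell. Under the slide block 534 genes were called, 478 of them shared in direction, and the dockerin median was 1.03, with 40 members higher and 1 lower. Within slide 2 the median was 1.09. Counts fell to 339 without CTN7 replicate 1, 327 without CTN7 replicate 2, 452 without DS3 replicate 1 and 385 with median scaling, and rose to 1445 when CTN5 replicate 2 was left out of the shared spread and 1399 with array weights. Dockerin rises dropped to 27 without either replicate of CTN7 and to 29 with median scaling.

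**Figure D2:**
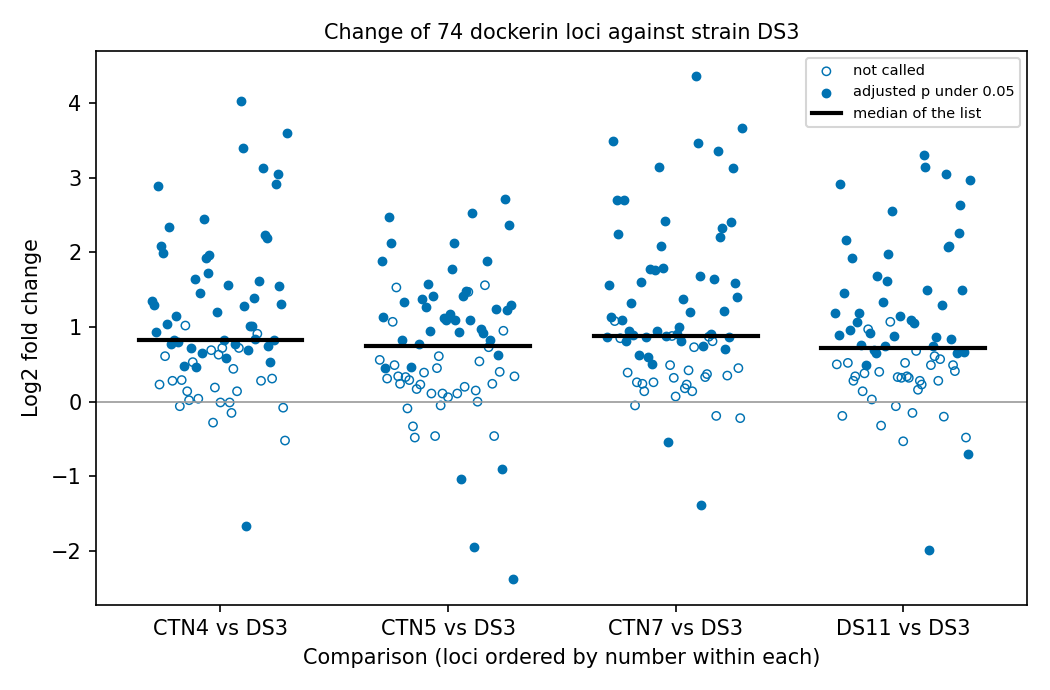
Log2 fold change (y axis) of the 74 dockerin loci in the 4 comparisons against DS3 (x axis), filled where adjusted p was under 0.05 and open otherwise, with a bar at the list's median. The medians were 0.82 in CTN4, 0.75 in CTN5, 0.89 in CTN7 and 0.71 in DS11.

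Comparing CTN5 with CTN4 set a strain with bright CipA against one with CipA below background, both with low surface scaffoldins. CipA was at least 41.3-fold higher in CTN5 (adjusted p = 1.48e-05). OlpC was higher by 0.80 (SE 0.17, adjusted p = 0.00678; 0.174 with median scaling, 0.0566 without the repeat arrays and 0.108 with array weights) and Cthe_0736 by 0.82 (SE 0.17, adjusted p = 0.00661; 0.113 with median scaling and 0.208 with array weights). Of the 74 dockerin loci 20 were lower in CTN5, 10 higher and 44 not called (18 and 9 called with slide as a block). Those lower in CTN5 included Cthe_3141, which fell by 3.27 (SE 0.38, adjusted p = 0.000527), Cthe_2138, which fell by 2.55 (SE 0.51), and Cthe_0044, which fell by 2.43 (SE 0.14). Cthe_2147 rose by 1.25 (SE 0.19; adjusted p = 0.0739 with array weights) and Cthe_3012 by 1.06 (SE 0.14). These dockerin loci were chosen after their values were seen. The dockerin list was not tested against other genes in this comparison, so its counts do not set it apart from them. By the fixed rule, Cthe_1531 was at least 7.52-fold and Cthe_1532 at least 8.08-fold higher in CTN5, Cthe_0446 was at least 6.19-fold lower. Cthe_0511 was also called lower, and was above background on only 1 of 3 arrays of CTN5. The adjusted p of Cthe_1531 was 0.012, and 0.0568 without CTN4 replicate 1 and 0.0615 without CTN4 replicate 2. In all, 1334 genes were called (451 higher, 883 lower). The model with a slide block called 1220, and 1181 of them were shared in direction. The count was 854 without CTN4 replicate 1 and 820 with median scaling.

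Both CTN7 and CTN4 had low CipA and low surface scaffoldins, and OlpC was at least 24.2-fold lower in CTN7 (adjusted p = 6.42e-06). In all, 38 genes were called (2 higher, 36 lower), 1 higher and 31 lower by 2-fold or more, and 498 had an unadjusted p under 0.05. Of the 74 dockerin loci 0 rose, 0 fell and 74 were not called, and with slide as a block 0 rose and 0 fell. Outside the scaffoldins, the largest fall by the fixed rule was that of Cthe_0508, by 2.29 (SE 0.26, adjusted p = 0.00647), which had an adjusted p from 0.0719 to 0.094 when any 1 of the 4 replicates was left out. The larger of the rises was that of Cthe_0960, by 1.40 (SE 0.23, adjusted p = 0.0326; 0.081 with median scaling and from 0.166 to 0.363 without any 1 replicate). A slide block left 29 called genes, 28 of them shared in direction. The count was 2 without CTN4 replicate 1, 11 without CTN4 replicate 2, 1 without CTN7 replicate 1, 3 without CTN7 replicate 2, and 5 with median scaling. It was 464 when CTN5 replicate 2, which is in neither strain but enters the shared estimate of the spread, was left out, and 756 with array weights, so the number of genes that differ between these strains is uncertain.

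Between CTN7 and CTN5, CipA was lower in CTN7 (adjusted p = 1.64e-05), where it was above background on only 1 of 3 arrays, and OlpC was at least 42.1-fold lower in CTN7. The dockerin list was not tested against other genes in this comparison either, so its counts do not set it apart from them. Of the 74 dockerin loci 18 were higher in CTN7, 8 lower and 48 not called (17 and 5 called with slide as a block). Among those chosen after their values were seen, Cthe_3141 was higher by 3.33 (SE 0.38, adjusted p = 0.000651), Cthe_0044 by 3.03 (SE 0.14) and Cthe_2138 by 2.89 (SE 0.51), while Cthe_1472 fell by 1.30 (SE 0.16) and Cthe_0640 fell by 1.01 (SE 0.15; adjusted p = 0.0696 with median scaling). By the fixed rule, Cthe_0511 was called higher, though above background on 1 of 3 arrays of CTN5, Cthe_0446 was at least 8.01-fold higher, and Cthe_1534 was at least 9.93-fold lower. In all, 1170 genes were called (777 higher, 393 lower), 487 higher and 241 lower by 2-fold or more. The slide block gave 1060 genes, 1016 of them shared in direction. The count was 1919 without CTN5 replicate 1, 593 without CTN7 replicate 1, 565 without CTN7 replicate 2, and 737 with median scaling.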

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

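Of the tests in this part, the 3 on CipA in CTN7 and the within-slide test of the dockerin list were chosen after the result was seen, as were the contrast between strain differences and the analysis of tiled regions.

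The CTN4 to CTN5 difference was set against the DS11 to DS3 difference, since in each the first strain has CipA below background and the second has it bright. This choice was made from CipA's levels. In the test of the difference itself 782 genes were called, 548 higher and 234 lower, and 564 with slide as a block, 551 of them shared. Without CTN5 replicate 2 the count was 1231. Of the 74 dockerin loci 22 were lower and 3 higher (18 and 2 with slide as a block), among them Cthe_2147 at -2.74 (SE 0.26) and Cthe_3136 at 2.56 (SE 0.24).

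The low quality of CTN5 replicate 2 is argued against as the source of the called dockerin differences. It stays open as a part of other differences. Without it, 99.4% of the 782 genes stayed called in the same direction. Leaving it out also narrows the shared estimate of the spread, so the share of calls kept cannot decide alone. Sizes do not depend on that spread. Without the replicate, the 22 lower dockerin loci lay from -0.80 to -2.76, against -0.74 to -2.74 with it. The 3 higher ones lay from 0.80 to 2.43, against 1.08 to 2.56 with it. Sizes without it were -2.76 for Cthe_2147 and 2.43 for Cthe_3136, while Cthe_0038 went from 4.86 to 3.84. Signals near the scanner's maximum do not account for the set, since 13.6% of the called genes had a strain above 50% of that maximum, against 14.5% of all genes. Among the 22 lower dockerin loci, however, 10 had such a strain, so compression at the bright end may shrink some of their differences. A biological difference between strain backgrounds stays open and untested. The pairs did differ beyond CipA. OlpB, Orf2p, OlpA and SdbA lay below background on every array of CTN4 and CTN5 and were bright in DS11 and DS3. Whether that underlies the set was not tested, and the labels do not give the genotypes.

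The dockerin list was higher than in DS3 in all 4 comparisons. Its median exceeded that of other genes by at least 0.63 log2 over the comparisons and 3 settings (median scaling, no background correction, mean of probes). Only median scaling replaced the quantile normalisation. Its excess of 0.68 in CTN4, 0.87 in CTN5, 0.90 in CTN7 and 0.84 in DS11 argues against quantile normalisation as the source. Median scaling shifts each array by a constant, which cancels in the excess, so a signal-dependent difference between arrays stays open. A slide difference as the whole cause is argued against, since the excess was at least 0.73 log2 within a slide, and with slide as a block 0.91 in CTN4, 0.83 in CTN5, 1.03 in CTN7 and 0.73 in DS11. For the CTN strains both values link to DS3 through the hazy DS3 repeat, the only DS3 array on slide 2, and with that array left out the excess, then across slides, was 0.63 in CTN4, 0.74 in CTN5 and 0.79 in CTN7. The 4 comparisons share the DS3 samples, so they are not independent, and a property of those samples could raise all 4 together. A biological difference between DS3 and the other strains may therefore underlie the pattern, as a hypothesis that these samples cannot separate from the state of the DS3 samples.

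On the first array of CTN7 replicate 1, CipA had 4.56% of its DS3 signal above background. Admixed RNA from a strain with CipA is argued against, since OlpC, bright in both strains with bright CipA, had 1.24% on that array. The repeat array with the same replicate number had 0.0681% of CipA, but it correlated better with replicate 2 (0.998) than with replicate 1 (0.991), so CipA transcript in that RNA stays open. A local defect, left open by a first test (13 of the 21 CipA spots raised, exact 95% interval 38.4% to 81.9%), is argued against by a later one, since of 101 random spots within 10 array positions of the raised CipA spots 7.92% lay above the array's background limit (exact 95% interval up to 15%), and 4 of the 7 CipA probes had all 3 of their separate spots raised. A biological cause was not tested beyond this.

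Tiled probes between genes, which the comparisons do not use, also gave signal. Joined within 100 bp and with at least 4 probes, they made 1473 regions, of which 157 (10.7%) lay above background on all 14 arrays. Against DS3, 20.2% of the regions were called in CTN4 (69.4% of them lower), 36.4% in CTN5 (54.1% lower), 17.0% in CTN7 (63.3% lower) and 24.4% in DS11 (40.1% lower). By a definition chosen after those counts were seen, regions called in the same direction both with and without slide as a block numbered 78 in CTN4, 230 in CTN5, 90 in CTN7 and 243 in DS11. The block alone called 5.5% of the regions in CTN4, 17.5% in CTN5, 6.5% in CTN7 and 16.6% in DS11. The region with probes starting from 3632171 to 3632766 on the chromosome of the design was called lower in CTN4, CTN5 and CTN7, where it lay below background on all 3 arrays of each strain, and was above it on every array of DS3 and DS11. That from 2916747 to 2916868 was called lower in DS11, below background on both of its arrays. The former region had the pattern of OlpB, Orf2p, OlpA and SdbA, so its low signal may likewise mark deleted DNA, which was not tested. The strand of these signals is unknown, because ds-cDNA was labelled.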

How the results depend on the processing

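Settings chosen only after the data were seen were the median of spots, the hazy DS3 array left out, CTN5 replicate 2 left out, repeats averaged with the other replicate, and array weights. For the comparisons against DS3 and between CTN strains, and for the planned lists that were tested, the changes are named here. Beyond them, counts of called genes stayed within 1.5 times and list calls held under every setting. The contrasts and lists chosen later were run under fewer settings, are outside this statement, and have their changes given in their own parts. The number of dockerin loci that rose moved further: median scaling gave 28 in CTN4 (47 before), 29 in CTN7 (47 before) and 26 in DS11 (40 before), leaving out the repeats 26 in DS11, array weights 20 in CTN5 (35 before), and leaving out 1 replicate as few as 28 in CTN4, 27 in CTN7 and 21 in DS11. The cause of the changes was not tested. Median scaling gave 456 genes for CTN4, 622 for CTN5, 385 for CTN7 and 608 for DS11 against DS3. It gave 820 for CTN5 against CTN4, 5 for CTN7 against CTN4 and 737 for CTN7 against CTN5. It moved the median change of all genes from 0.16 to 0.31 in CTN4 against DS3, so changes there are better read against other genes. The slide block gave 516 for CTN4 against DS3. The replicate numbers did not pair the samples (correlations of deviations from -0.183 to 0.152), and the replicate block gave 21 for CTN7 against CTN4 and moved no other count by over 1.5 times. Leaving out the repeats gave 20 there. An estimated correlation left 1 list called for CTN5. Array weights gave 514 for CTN5, 1399 for CTN7 and 1477 for DS11 against DS3, 685 for CTN5 against CTN4, 756 (313 higher, 443 lower) for CTN7 against CTN4 and 633 for CTN7 against CTN5. Without CTN5 replicate 2 in the shared spread, 1528 genes were called for CTN4, 1445 for CTN7 and 1632 for DS11 against DS3, and 464 (187 higher, 277 lower) for CTN7 against CTN4. Leaving out 1 replicate at a time, with the lone sample assumed to vary like the other strains, gave 447 to 593 for CTN4, 777 to 1853 for CTN5, 327 to 548 for CTN7 and 567 to 703 for DS11 against DS3. It gave 854 to 1980 for CTN5 against CTN4, 1 to 11 for CTN7 against CTN4 and 565 to 1919 for CTN7 against CTN5. Lists called were 2 to 2 for CTN4, 1 to 2 for CTN5, 2 to 2 for CTN7 and 1 to 1 for DS11. Scaffoldin calls ranged from 19 to 26. Signs turned in uncalled genes. OlpC in CTN5 against DS3 was 0.10 with median scaling, 0.026 with the mean of probes, 0.069 with the slide block, 0.09 without CTN5 replicate 2, 0.15 without DS3 replicate 1 and -0.19 without DS3 replicate 2. CipA in CTN5 was -0.46 with the slide block, Cthe_3141 in CTN5 -0.35 without CTN5 replicate 1 and 1.03 without CTN5 replicate 2 (called only there, adjusted p = 0.00161), and Cthe_0736 in DS11 0.019 without DS11 replicate 2 and -0.39 without DS11 replicate 1. Of the other values of named genes, 2320 kept their side of the threshold, 83 lost and 16 gained a call. The dim filter removed 28 genes and left 3037. Of the 4 dockerin loci above 50% of the scanner's maximum in DS3, 0 of 4 rose in each comparison (limma), and whether a ceiling held them was not tested.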

Other observations

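All tests in this part were chosen after the data were seen. A list of 16 sigI and rsgI loci, which encode alternative sigma factors and membrane anti-sigma factors that sense polysaccharides, was assigned from memory and checked against no table. So were lists of 6 glycosidase loci thought to lack a dockerin and 8 loci of cellodextrin use and fermentation. Raw signals of the scaffoldins had been seen by then, but no fit. In CTN7, 10 sigI and rsgI loci rose and 1 fell (camera adjusted p = 0.00206, and adjusted p = 0.138 with an estimated correlation). In CTN4, 9 rose and 0 fell (adjusted p = 0.0143, and adjusted p = 0.239 with an estimated correlation). In CTN5, 8 rose and 1 fell (adjusted p = 0.0524), and in DS11, 6 rose and 1 fell (adjusted p = 0.0562). With slide as a block the rises numbered 6 in CTN7, 5 in CTN4, 7 in CTN5 and 6 in DS11. Of the 6 glycosidase loci, 3 rose in CTN5 (adjusted p = 0.0124, and adjusted p = 0.147 with an estimated correlation; 4 rose with slide as a block) and 0 fell. In CTN7 3 rose and 1 fell (adjusted p = 0.102), and 1 rose and 1 fell in each of CTN4 (0.452) and DS11 (0.618). The list of cellodextrin use and fermentation was called in no comparison with camera (adjusted p = 0.452 in CTN4, 0.257 in CTN5, 0.635 in CTN7 and 0.789 in DS11), and 1 of its 8 loci rose in each of CTN4, CTN7 and DS11 while 1 fell in CTN5.

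CTN4 and DS11 both have CipA below background, and 218 genes differed between them (177 higher in CTN4, 41 lower). With slide as a block 40 were called, 37 of them shared, and without CTN5 replicate 2, which is in neither strain, 891 were called. No array of both strains shared a slide. Of the dockerin loci, 3 were higher in CTN4 by this test and 0 with slide as a block.

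Cthe_2089, a dockerin locus chosen after its values were seen, had 62.5% of the scanner's maximum in DS3, and its log2 changes were 0.14 in CTN4, 0.20 in CTN5, 0.14 in CTN7 and 0.28 in DS11, none called.

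Of the 4 repeat arrays, 3 correlated better across genes with the replicate of the other number. The CTN4 repeat, numbered 2, correlated at 0.991 with replicate 1 and 0.975 with replicate 2. For DS3 the values were 0.987 with replicate 2 and 0.974 with its own number, 1. Averaging each repeat with the other replicate gave 943 called genes for CTN4, 1149 for CTN5, 888 for CTN7 and 1052 for DS11 against DS3. Without the repeats the counts were 692 for CTN4, 927 for CTN5, 531 for CTN7 and 753 for DS11. Averaged by number, they were 873, 1206, 777 and 965. A mixed-up number may lie behind these correlations, but the dim first array of CTN4 replicate 2 is also an open explanation in CTN4. If numbers were mixed up, averaging by number blends the replicates of a strain, and the spread may then be underestimated.

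The DS3 repeat array had 16.6% of random spots above 3 times their median and the array of CTN5 replicate 2 had 14.7%, against at most 6.92% on the others.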
